A study of Mus musculus with 7 samples.

How the data were processed

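Brains were taken at postnatal day 30 from mice of strain B6129SF1/J, and the ventromedial prefrontal cortex and the motor cortex were excised by hand and dissociated, per the labels' protocols. Droplet libraries were made with 10x Genomics 3' chemistry. Cell Ranger 3.0.2, Seurat and the mm10 genome are named in the submitters' processing notes, and the role of each is not given in the sources used here. The deposited tables hold counts of unique molecular identifiers (UMIs) per gene and cell, and all values were checked to be whole numbers of at least 0. Samples were grouped by the area and genotype of their labels into 4 groups of 2, 3, 1 and 1 libraries.

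Each library's fewest genes per cell lay between 501 and 503, so the filter of at least 200 genes and at most 20% mitochondrial counts removed 0 cells. Scrublet scores, as carried by scanpy 1.11.5, gave doublet calls per library. Where the automatic threshold called under 0.5% or over 15% of a library, the top-scoring 0.8% per 1000 cells were taken instead. This applied to PFC DTA replicate 3, where the automatic threshold called 4 cells. The calls numbered 23 and 474 in PFC CTRL, 87, 70 and 295 in PFC DTA, 207 in MC CTRL and 26 in MC DTA, and these cells were removed.

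All 7 libraries were clustered together without batch correction. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes and 30 principal components were used. Neighbours (20 per cell) were joined where their Jaccard overlap was above 1/15, and leidenalg 0.10.2 was run at a resolution of 1.0 with seed 1. Clusters were named from marker genes of 19 classes, so that a name stands for cells like that type. A marker counted as detected at 20 CPM or more and 2-fold above the other cells, and at least 3 had to be detected. A cluster stayed unnamed where its leading genes went against the name, where a second class reached a relative level above 0.45, or where over 50% of its cells were called doublets. The level of 0.45 was set after the clusters had been seen, and so the unnamed share is given per library. In the end 8 classes had at least 30 cells in every library. Within them the counts per library ranged from 3488539 to 21574209 in excitatory neurons and from 151100 to 933903 in microglia. They ranged from 339706 to 3343967 in inhibitory neurons and from 373169 to 1552957 in astrocytes.

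Counts were summed per library and class. Genes were kept by filterByExpr at 10 counts, scaled by TMM and tested with edgeR 4.0.16 (robust quasi-likelihood test), and p-values were adjusted by Benjamini-Hochberg within a class at a threshold of 0.05. The PFC genotypes were compared within the 5 PFC libraries, with 3 residual degrees of freedom. The areas were compared in all 7 libraries with genotype as a term. The SE of a fold change was derived from this test, as the absolute log2 fold change divided by the square root of its F statistic. Intervals of PFC fold changes rest on that SE. DESeq2 1.42.0 was run as a second tool. Gene lists with at least 5 tested members were tested with camera of limma 3.58.1 at a correlation of 0.01, adjusted over all 113 tests of lists by class. Counts of members past the threshold are given over all genes and adjusted over the list alone. Class shares were tested with edgeR on numbers of cells and with an exact two-sided permutation test over the 10 ways to choose the CTRL libraries. In the MC, log2 ratios carry exact Poisson intervals at 95% confidence. A list's median there was set among 10000 random lists drawn from 20 expression bins.

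The tests, the markers, 27 gene lists and the rule for naming genes were fixed before the data were examined. Under that rule, a PFC class gives the 3 genes with the largest fold each way among those past the threshold, with groups apart and a mean of at least 20 CPM. With fewer than 2 such genes, the 2 with the smallest p each way are named in the 3 classes with the most cells. Lists give their called members by p, or the 2 with the smallest p. The MC gives the genes named for the PFC and the 3 largest ratios each way among genes with at least 50 counts in each library. The area comparison gives the 3 largest folds each way past the threshold with a mean of at least 20 CPM. Predicted genes and pseudogenes were counted and not named. Some genes under this rule, and 1 test that used marker genes, are not reported here.

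Alternatives were other size factors (RLE), no filter on low counts, a test that is not robust, doublets kept, every deposited cell kept, resolutions of 0.5 and 2.0, equal numbers of cells per library, the replicate number as a block, an estimated correlation for lists, the library total in place of TMM in the MC, and each library left out. A term for the deep and shallow libraries, and shares of named cells only or of neurons only, were added after seeing the data.

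The tests were checked on simulated data drawn from the real means and library sizes with 200 changed genes, 100 of them at each fold. The changed genes were drawn only among genes above a minimum mean count, so the shares found do not hold for all tested genes. Genes were drawn independently of each other. Over the PFC classes, 14 to 60 of 100 genes changed 2-fold and 87 to 99 of 100 changed 4-fold were found. False calls were 10 of 166 calls in excitatory neurons (13674 genes), 17 of 175 in inhibitory neurons, 19 of 137 in astrocytes, 13 of 146 in oligodendrocytes, 14 of 121 in newly formed oligodendrocytes, 8 of 142 in precursors, 7 of 117 in endothelial cells and 10 of 111 in microglia (6225 genes). For the areas in excitatory neurons, 80 and 98 of 100 were found with 19 false calls of 197 (13940 genes). Further tools were R 4.3.3, its package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.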

Results

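Single-cell RNA sequencing was carried out on the ventromedial prefrontal cortex (PFC) and the motor cortex (MC) of mice at postnatal day 30, kept under 12 h of light and 12 h of dark. Mice of the control genotype (CTRL; Opn4-Cre/+; Brn3b-+/+) keep their intrinsically photosensitive retinal ganglion cells, the melanopsin-expressing neurons of the retina that send light signals to the brain. In the second genotype (DTA; Opn4-Cre/+; Brn3b-zDTA/+), diphtheria toxin subunit A is meant to ablate those of them that also express Brn3b. The PFC was measured in 2 CTRL and 3 DTA libraries, and the MC in 1 library of each genotype. The data hold 11815 PFC CTRL cells, 12568 PFC DTA cells, 6229 MC CTRL cells and 2373 MC DTA cells, the numbers the series states. Total UMI counts were 14065003 and 30324460 in PFC CTRL replicates 1 and 2. They were 6180059, 30972905 and 26552256 in PFC DTA replicates 1 to 3, 25214785 in MC CTRL and 20770393 in MC DTA. P-values below from edgeR, DESeq2 and the permutation test measure the spread between libraries, and the labels describe the brain extracted for each sample. Those from camera at a preset correlation set the genes of a list against the other genes. They take the correlation between genes as given, so they do not cover the spread of a whole list between libraries.

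The transcripts that differ between the sexes were alike in all 7 libraries. Ddx3y, a Y-linked RNA helicase gene, stood at 69.8 to 86.0 CPM (counts scaled to the library total), Eif2s3y at 64.1 to 90.0, Kdm5d at 13.4 to 20.1 and Uty at 11.2 to 18.0. Xist, the RNA that silences an X chromosome in females, had 0 to 5 counts per library, and Tsix, its antisense partner, also had 0 to 5 counts; reads of this pair may not be separable. In the shallowest library 3 counts amount to 0.50 CPM. The targeted loci Opn4 and Pou4f2 were not analysed here.

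The libraries fell into a deep and a shallow set. Median UMI counts per excitatory neuron were 11457 in PFC CTRL replicate 1, 12508.5 in PFC DTA replicate 2 and 15841.5 in MC DTA. In PFC CTRL replicate 2, PFC DTA replicates 1 and 3 and MC CTRL they were 3565, 4104, 5612 and 5413. Each PFC genotype thus had libraries of both sets. In the PFC, CTRL replicate 1 was the only deep and CTRL replicate 2 the only shallow CTRL library. Differences within a set therefore lack CTRL replicates. The sets were formed from excitatory neurons alone and used for every class, and other classes did not all follow them. In oligodendrocytes the shallow PFC DTA replicate 3 had 2531421 counts in 290 cells. That is more per cell than in the deep PFC CTRL replicate 1 (719048 in 112) and PFC DTA replicate 2 (635204 in 108). Transcripts of blood cells also differed between libraries. S100a8, which encodes a calcium-binding protein of neutrophils, stood at 57.4, 2.72, 45.6, 51.5 and 94.3 CPM over all cells of the PFC libraries in the order above. It stood at 3.23 CPM in MC CTRL and 52.0 CPM in MC DTA. Hba-a1, a haemoglobin gene of red blood cells, ranged from 406 CPM in PFC CTRL replicate 2 to 1778 CPM in MC DTA. Malat1, a nuclear RNA, stood at 58900 CPM in the excitatory neurons of PFC DTA replicate 3 and at 20570 to 23090 CPM in those of the other PFC libraries.

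The first comparison asks whether the cell composition of the PFC differs after ablation. Excitatory neurons, the glutamatergic projection cells of the cortex, made up 42.8% ± 4.80 (SD, n = 2) of CTRL cells and 34.3% ± 8.01 (SD, n = 3) of DTA cells. Inhibitory neurons, which release GABA, made up 10.1% ± 3.04 (SD, n = 2) and 5.60% ± 1.86 (SD, n = 3). Astrocytes, the glia that take up transmitter, held 12.5% ± 0.716 and 12.2% ± 3.46. Microglia, the resident immune cells, held 7.63% ± 2.0 and 5.81% ± 1.89. Myelinating oligodendrocytes held 5.41% ± 0.629 and 5.16% ± 2.39, their precursors 4.73% ± 1.22 and 4.14% ± 1.68, newly formed oligodendrocytes 2.01% ± 0.185 and 1.85% ± 1.0, and endothelial cells, the lining of blood vessels, 6.34% ± 2.94 and 5.17% ± 2.39. All these shares are of kept cells including unnamed clusters, whose mean share was 3.77% in CTRL and 21.6% in DTA. A larger unnamed share lowers those of the named classes, so a lower share in DTA may not be a loss of that class. No named class differed past the threshold by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The adjusted p was 0.735 for inhibitory neurons (exact permutation p 0.2). For neuroblasts or progenitors, at 0.300% ± 0.0933 and 0.888% ± 0.553, it was 0.218 (exact permutation p 0.3). With 2 libraries against 3, the exact two-sided permutation test cannot give a p below 0.1, and the libraries differ in depth per cell as given above, which can set shares as well.

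**Figure D1:**
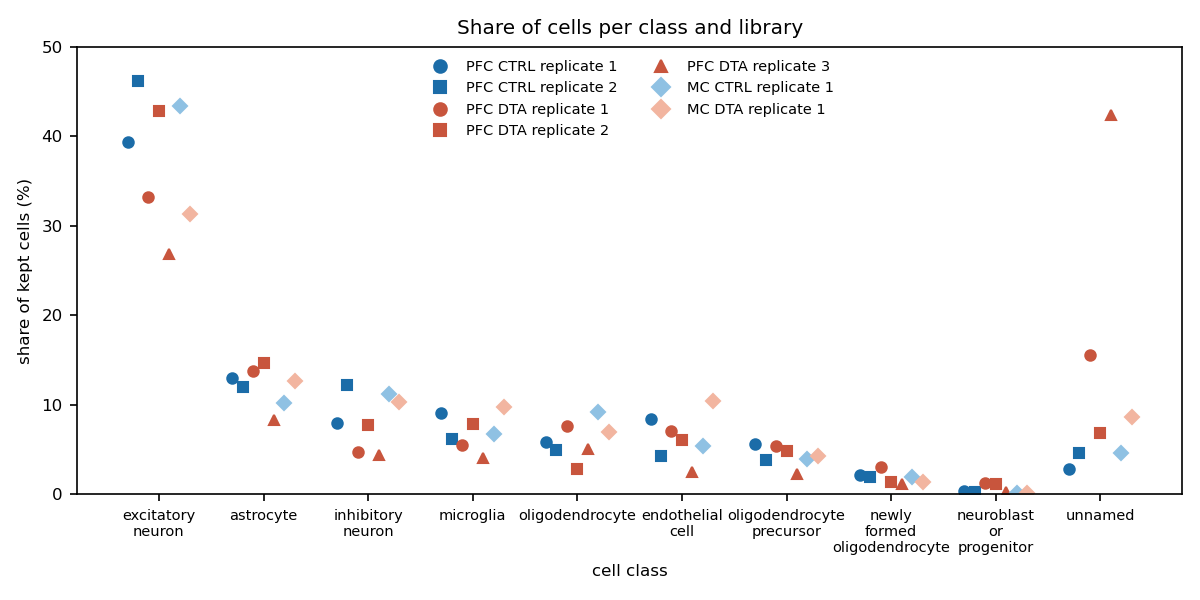
Share of kept cells (%) per cell class, 1 point per library, for the 4 groups. The unnamed share of PFC DTA replicate 3 (42.4%) lies far above those of the CTRL libraries (2.88% and 4.67%).

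Unnamed clusters held 3.77% ± 1.27 (SD, n = 2) of CTRL cells and 21.6% ± 18.5 (SD, n = 3) of DTA cells. The edgeR adjusted p was 0.00699 and the exact permutation p 0.2. The share was 2.88% and 4.67% in CTRL replicates 1 and 2, and 15.5%, 6.81% and 42.4% in DTA replicates 1 to 3. Over the PFC libraries together, most of these cells belonged to a cluster led by the haemoglobin genes Hba-a2, Hbb-bt and Hba-a1 together with neuronal genes, at a median of 762 UMIs per cell. It held 0.732%, 3.55%, 12.6%, 2.13% and 33.0% of the PFC libraries, and 2.61% and 2.51% of MC CTRL and MC DTA. A second unnamed cluster, led by the neutrophil genes S100a8, S100a9 and Camp, held 7.03% of PFC DTA replicate 3 and 0.0213% to 0.789% of the other PFC libraries. An unnamed cluster with astrocyte and excitatory neuron genes was larger than the first in CTRL replicate 1 (1.10%) and DTA replicate 2 (3.05%). The unnamed share did not stay past the threshold without CTRL replicate 1 (edgeR adjusted p 0.724), CTRL replicate 2 (0.261), DTA replicate 1 (0.0546) or DTA replicate 3 (0.0793). The level of a second class above which a cluster stays unnamed was set after the clusters had been seen.

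Among neurons alone, inhibitory neurons held a lower share in each PFC DTA library than in each CTRL library. The share of neurons that were inhibitory was 18.9% ± 2.94 (SD, n = 2) in CTRL and 13.9% ± 1.46 (SD, n = 3) in DTA, a difference of -5.00 percentage points with an exact two-sided permutation p of 0.1, the smallest this design allows. By library, with exact Clopper-Pearson 95% intervals, it was 16.8% (14.4 to 19.4) and 21% (19.9 to 22.1) in CTRL. In DTA it was 12.4% (10.4 to 14.6), 15.3% (13.7 to 17) and 14% (12.4 to 15.6). The intervals of the deep libraries, CTRL replicate 1 and DTA replicate 2, overlapped. In the MC, the share of neurons that were inhibitory was 20.5% (19.1 to 21.9) in the CTRL library and 24.7% (22.1 to 27.6) in the DTA library.

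**Figure D2:**
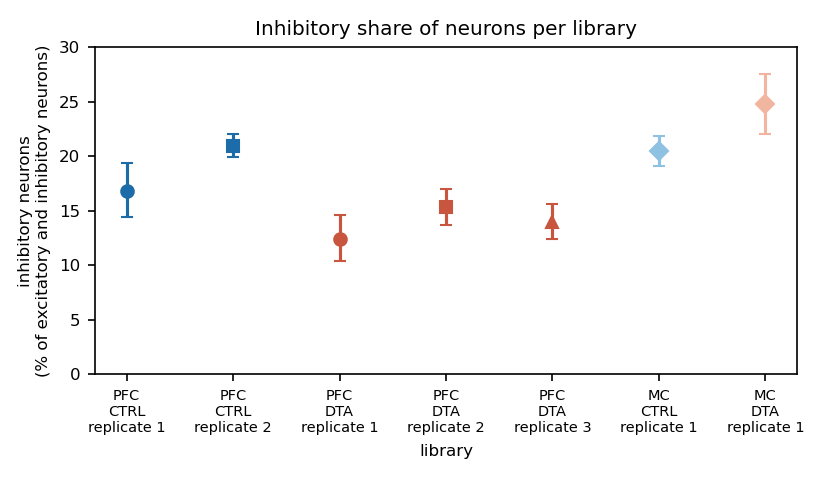
Inhibitory neurons as a percentage of excitatory and inhibitory neurons, 1 point per library with its exact Clopper-Pearson 95% interval. The PFC DTA libraries lie at 12.4% to 15.3% and the PFC CTRL libraries at 16.8% and 21%, whereas MC DTA (24.7%) lies above MC CTRL (20.5%).

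The second comparison asks which genes respond to ablation in each cell class of the PFC, and no gene passed the threshold in any of the 8 classes. In excitatory neurons, Cort, which encodes the inhibitory neuropeptide cortistatin, was lower by the smallest p (log2 fold change -1.12, SE 0.232; 11.8 ± 0.227 CPM in 2 CTRL and 5.27 ± 0.923 CPM in 3 DTA libraries, SD), with an edgeR adjusted p of 0.999. Cd24a, which encodes a surface protein of young neurons, followed at -0.55 (SE 0.151). On the higher side stood S100a6, a calcium-binding protein gene, at 0.72 (SE 0.165) and Grm2, the gene of a presynaptic glutamate receptor, at 0.77 (SE 0.201). In astrocytes the complement gene C4b, whose counts may include its paralog C4a, was higher at 1.92 (SE 0.407; 10.0 ± 2.71 against 41.2 ± 14.4 CPM). The mitochondrial ATP synthase gene mt-Atp8, which overlaps mt-Atp6, was higher at 2.06 (SE 0.432). Cables1 and Plk2, genes of a cell cycle regulator and a synaptic kinase, were lower at -1.02 (SE 0.278) and -1.14 (SE 0.312). In inhibitory neurons Kif22, a kinesin gene, was higher at 1.52 (SE 0.340) and the glycolysis gene Eno1, which may share reads with Eno1b, at 0.92 (SE 0.208). C1qa, a complement gene made by microglia, was lower there at -1.84 (SE 0.463), as was St8sia4, the gene of a polysialic acid enzyme, at -0.80 (SE 0.223). By the main test none of these 12 genes passed, with adjusted p-values of 0.970 to 1.0 by edgeR. Kif22 passed when CTRL replicate 1 was left out (1.98), with the replicate number as a block (1.76) and with no filter on low counts (1.51). C4b, mt-Atp8 and Eno1 also passed with no filter (1.94, 2.08 and 0.91).

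By edgeR the count of genes past the threshold was 0 in each class, while at an unadjusted p under 0.05 there were 252 genes in excitatory neurons, 435 in inhibitory neurons, 286 in astrocytes and 213 in oligodendrocytes. There were 117 in newly formed oligodendrocytes, 286 in oligodendrocyte precursors, 154 in microglia and 113 in endothelial cells. DESeq2 called 0 genes in each class but astrocytes, where it called 1, the non-coding gene Snhg9 (log2 fold change 2.31, DESeq2 adjusted p 0.00533). Summed over all cells the counts were 0 by edgeR, 342 at an unadjusted p under 0.05, and 1 by DESeq2, 1500015O10Rik (2.83, adjusted p 0.0438). Both genes were singled out after their values were seen. The groups did not overlap in 13.7% to 17.6% of genes per class, where chance gives 20%. The interval of the fold change lay within 2-fold either way for 77.0% of the 13893 genes of excitatory neurons, and for 31.8% of the 6628 genes of microglia. Leaving out a library moved the sum over classes to 300 genes without CTRL replicate 1 and 110 without CTRL replicate 2. Oligodendrocytes held 189 and 75 of these. The sum was 1, 3 and 1 without DTA replicates 1, 2 and 3: AC160336.1, then Ddit4l, Tmem215 and Klf4, then Yjefn3, all singled out after their values were seen. In simulated data with 200 changed genes, all with a mean of at least 20 counts per library, the test was run again. It found 57 of 100 genes changed 2-fold and 99 of 100 changed 4-fold in excitatory neurons. In microglia it found 14 and 87.

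Gene lists gave calls where edgeR called no single gene. In 113 tests of gene lists across the 8 classes, camera at a preset correlation of 0.01 called 47, of which 39 were higher and 8 lower in DTA. Other splits of the 5 PFC libraries into 2 and 3 gave 22 to 43 calls by the same test, with a median of 33. With the correlation estimated from the libraries none was called, and the smallest adjusted p was 0.702. No list held a gene past the threshold over all genes tested. The 7 list results that come next kept their call in every setting tried but the estimated correlation, including with each library left out. Every other called list lost it in at least 1 further setting.

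In microglia the inflammatory cytokine genes, which encode the signals of an activated immune cell, rose in DTA, with 16 of 16 members higher at a median log2 fold change of 1.44 (camera adjusted p 1.41e-12). The adjusted p was 0.702 with an estimated correlation. Cxcl2, a chemokine gene that recruits neutrophils, was higher at 2.03 (SE 0.498; 117 ± 68.6 CPM in 2 CTRL and 488 ± 265 CPM in 3 DTA libraries, SD), and Tnf at 1.11 (SE 0.354; 247 ± 85.5 and 533 ± 165 CPM). Adjusted over the list alone, 1 member passed. What raised these genes was not tested, and the cells had been dissociated. The list median was 0.53 without DTA replicate 3. The activated microglia list, genes of phagocytosis and lysosomes, rose by a median of 0.51 with 12 of 12 members higher (camera adjusted p 8.88e-05; 0.702 with an estimated correlation). Its members Ctsl and Cst7, a lysosomal protease and its inhibitor, stood at 0.59 (SE 0.356) and 0.78 (SE 0.480), and 0 members passed adjusted over the list alone. Its median was 0.24 without CTRL replicate 2 and 0.31 without DTA replicate 1. The mitochondrially encoded genes rose by a median of 0.38 with 12 of 12 higher (1.46e-08; 0.702 with an estimated correlation), led by mt-Nd4l and mt-Atp8, both of which overlap a neighbouring gene, and 3 passed adjusted over the list alone. Microglia of different libraries came mostly from different clusters. Cluster 16, led by Ccl4, a chemokine gene of the cytokine list that is also a leading gene of cluster 9, held 74.0% and 2.56% of the microglia of CTRL replicates 1 and 2. It held 1.44%, 82.9% and 54.9% of those of DTA replicates 1 to 3, with the remainder in cluster 9. The median UMI counts per cell were 2942 in cluster 16 and 1328 in cluster 9, and Ccl4 itself stood at 1427, 3827, 2502, 4826 and 17010 CPM.

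In astrocytes the reactive astrocyte list, genes switched on after injury, rose by a median of 1.03 with 7 of 8 members higher (camera adjusted p 4.97e-09; 0.702 with an estimated correlation). It was led by C4b and by Vim, an intermediate filament gene (0.85, SE 0.250; 72.4 ± 8.0 CPM in 2 CTRL and 127 ± 29.7 CPM in 3 DTA libraries, SD), and 4 members passed adjusted over the list alone. The median was 0.60 without CTRL replicate 2 and 0.63 without DTA replicate 3. Ribosomal protein genes, whose counts may include those of pseudogenes, rose by a median of 0.19 with 67 of 73 higher (3.73e-10; 0.760 with an estimated correlation), led by Rps29 at 1.22 (SE 0.327) and Rpl38 at 1.0 (SE 0.282); 0 passed adjusted over the list alone. That median was 0.09 without DTA replicate 2 and 0.36 without DTA replicate 3. Mitochondrially encoded genes rose by a median of 0.26 with 13 of 13 higher (1.77e-08; 0.702 with an estimated correlation; median 0.45 without CTRL replicate 1), and 3 passed adjusted over the list alone. A cluster led by Gfap and Myoc, genes of fibrous astrocytes, held 2.02% and 3.38% of CTRL astrocytes and 3.44%, 3.58% and 11.5% of DTA astrocytes. Most astrocytes of CTRL replicate 2 and DTA replicate 1 lay in cluster 3 (90.7% and 90.0%), and most of CTRL replicate 1 and DTA replicates 2 and 3 in cluster 10 (82.7%, 77.8% and 55.9%).

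In endothelial cells the genes of class I antigen presentation, which show peptides to T cells, rose by a median of 0.53 with 10 of 10 members higher (camera adjusted p 2.11e-07; 0.702 with an estimated correlation). H2-Q4 stood at 1.81 (SE 0.434; 14.1 ± 2.15 CPM in 2 CTRL and 48.0 ± 17.2 CPM in 3 DTA libraries, SD) and H2-K1 at 0.80 (SE 0.308; 198 ± 61.1 and 345 ± 108 CPM). Reads of this gene family may be split between near-identical members, and 1 member passed adjusted over the list alone. The median was 0.35 without DTA replicate 1 and 0.80 without DTA replicate 3. The list was higher by 0.53 within the deep and by 0.57 within the shallow libraries. Summed over the list, CPM stood at 2175 and 1968 in the CTRL libraries and at 3968, 2659 and 2677 in the DTA libraries. In the same endothelial cells, 7 leukocyte genes summed to 32.2, 56.2, 75.1, 148 and 29.2 CPM. The blood-brain barrier list, transporters and junction genes of these cells, had a median of -0.03 (camera adjusted p 0.766).

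**Figure D3:**
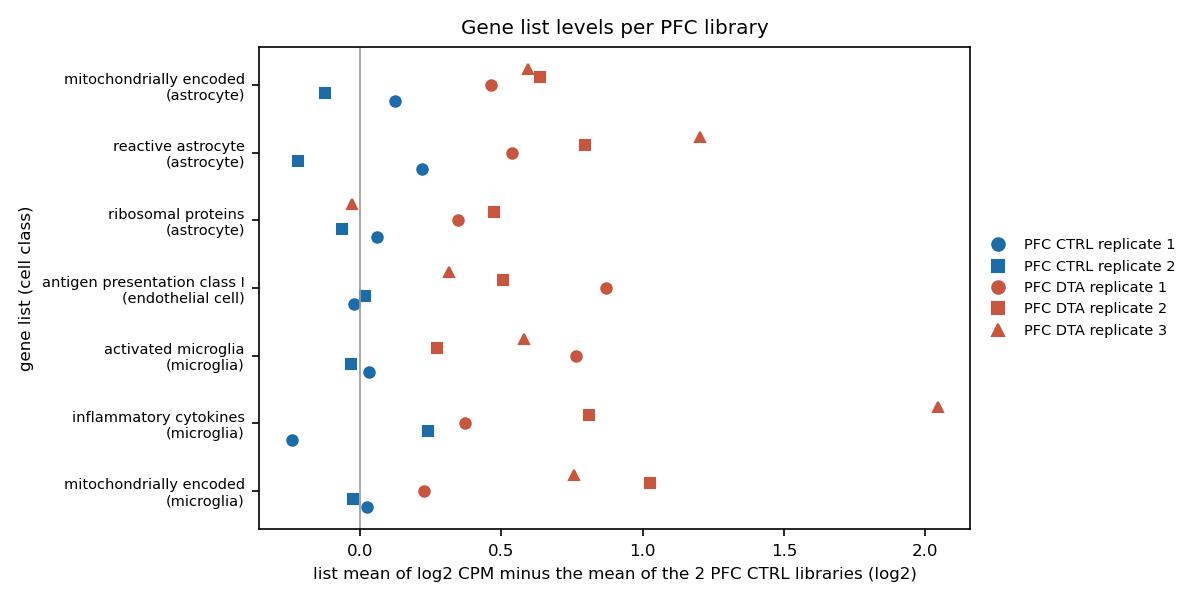
Mean log2 CPM of each of the 7 gene lists in the 5 PFC libraries, as the difference from the mean of the 2 CTRL libraries (log2). The median log2 fold changes of these lists lie between 0.19 (ribosomal proteins in astrocytes) and 1.44 (inflammatory cytokines in microglia).

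Lists of energy and translation genes were called in most classes at the preset correlation. Ribosomal protein genes rose in the other 7 classes too, with medians from 0.07 in excitatory neurons (camera adjusted p 0.0183; 0.923 with an estimated correlation) to 0.38 in microglia (1.59e-07; 0.80). These calls were lost when some single libraries were left out. Without CTRL replicate 2 the median was -0.06 in excitatory neurons, -0.05 in endothelial cells, 0.06 in inhibitory neurons, 0.04 in oligodendrocytes and 0.07 in newly formed oligodendrocytes. Without DTA replicate 2 it was 0.00 in oligodendrocyte precursors, 0.10 in microglia and -0.02 in excitatory neurons, where it was also -0.02 without DTA replicate 1, and each of these calls was lost. Calls were kept at lower medians without DTA replicate 1 in inhibitory neurons (0.12), microglia (0.21) and newly formed oligodendrocytes (0.09), without DTA replicate 2 in the latter (0.12) and in oligodendrocytes (0.11), and without CTRL replicate 2 in precursors (0.13) and microglia (0.24). Medians were highest without CTRL replicate 1 or DTA replicate 3, at 0.23 to 0.67 by class. Adjusted over the list alone, 1 gene passed in oligodendrocyte precursors, Rps29 (1.25, SE 0.298; edgeR adjusted p 0.732 over all genes), and 0 in the other 6. 

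Nuclear genes of oxidative phosphorylation, which build the respiratory chain, rose by a median of 0.20 in inhibitory neurons with 59 of 65 higher (camera adjusted p 9.43e-07; 0.80 with an estimated correlation), led by Atp5k at 0.74 (SE 0.257). They rose by 0.16 in excitatory neurons, 0.17 in oligodendrocytes, 0.20 in newly formed oligodendrocytes, 0.13 in astrocytes, 0.11 in oligodendrocyte precursors and 0.18 in microglia. With an estimated correlation the adjusted p of these was 0.702 to 0.801, and no member passed adjusted over the list alone. Without CTRL replicate 2 the medians were -0.08 in inhibitory neurons, -0.05 in excitatory neurons, 0.03 in oligodendrocytes, 0.13 in newly formed oligodendrocytes and 0.04 in astrocytes. Without DTA replicate 1 they were 0.04, 0.03, 0.06 and 0.08 in inhibitory neurons, excitatory neurons, astrocytes and precursors, and without DTA replicate 2 the precursors had 0.09. Microglia had 0.13, 0.14 and 0.10 without CTRL replicate 1, DTA replicate 2 and DTA replicate 3, and all of these calls were lost. In oligodendrocytes the call was kept without DTA replicate 1 at 0.08. Without CTRL replicate 1 the medians were 0.48, 0.41, 0.30 and 0.29 in inhibitory neurons, excitatory neurons, oligodendrocytes and astrocytes. The direction differed between the depth sets. Within the deep libraries the list was lower by 0.17, 0.09 and 0.01 in inhibitory neurons, excitatory neurons and astrocytes. Within the shallow ones it was higher by 0.55, 0.42 and 0.25. The sets rest on CTRL replicate 1 (deep) and CTRL replicate 2 (shallow), so depth cannot be told here from a difference between these libraries. In endothelial cells this list had a median of 0.01 (adjusted p 0.460). The mitochondrially encoded list was also called as higher in oligodendrocytes, newly formed oligodendrocytes and endothelial cells, with 12 of 12 members higher in each, and in excitatory neurons, with 7 of 13 higher. The medians were 0.16, 0.17, 0.20 and 0.03 (0.750, 0.750, 0.750 and 0.801 with an estimated correlation). None of these calls held without CTRL replicate 2 (-0.08, 0.10, 0.06 and -0.02), nor did those in endothelial cells and excitatory neurons without DTA replicate 2 (0.16 and -0.10). Those in oligodendrocytes and newly formed oligodendrocytes were kept without it at 0.09 and 0.10. Adjusted over the list alone, 1, 1, 0 and 0 members passed. The list was not called in oligodendrocyte precursors (median 0.14, adjusted p 0.0952), and in inhibitory neurons its median was -0.22, its mean 0.06 and its direction lower by the test (adjusted p 0.550).

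The list of immediate early genes was called in inhibitory neurons at the preset correlation. These genes, which follow recent stimulation of a cell, rose by a median of 0.79 with 20 of 23 higher (camera adjusted p 8.40e-06, and 0.750 with an estimated correlation). Klf4 stood at 2.32 (SE 0.550) and Ier3 at 0.79 (SE 0.297), and 0 passed adjusted over the list alone. All cells had been dissociated, and what set off these genes, here or in glia, was not tested. The list was lower by 0.20 within the deep and higher by 1.30 within the shallow libraries, and its call was lost without CTRL replicate 2 (median 0.78). The median was 0.11 without DTA replicate 3, 1.39 without CTRL replicate 1 and 1.20 without DTA replicate 2. Fos, a member of it, stood at 274 and 115 CPM in CTRL and at 312, 215 and 864 CPM in DTA. In excitatory neurons this list had a median of -0.02, a mean of 0.05 and a direction of higher by the test (adjusted p 0.219). It was lower by 0.66 within the deep and higher by 0.86 within the shallow libraries. A cluster led by early genes, cluster 8, held 14.7% and 8.55% of the excitatory neurons of CTRL and 10.1%, 17.4% and 32.1% of those of DTA.

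The early gene list was called in glia as well. The list rose in astrocytes by a median of 0.25 (camera adjusted p 0.000197; 0.702 with an estimated correlation), in oligodendrocytes by 0.23 (0.00473; 0.750), in oligodendrocyte precursors by 0.57 (0.00989; 0.80) and in microglia by 0.40 (0.0183; 0.702). In endothelial cells it fell by -0.16 (0.0156; 0.702), with the flow-responsive gene Klf2 at -0.90 (SE 0.344). Fosb, a transcription factor gene, stood at 1.33 (SE 0.342) in astrocytes, Egr2 at 0.85 (SE 0.371) in oligodendrocytes, Jun at 0.93 (SE 0.353) in precursors and the stress gene Atf3 at 1.15 (SE 0.437) in microglia. Adjusted over the list alone, 0 members passed in each of these 5 classes. The astrocyte call was lost without CTRL replicate 2 (0.49) and kept at 0.12 without DTA replicate 1. In oligodendrocytes the list was higher by 0.60 within the deep and lower by 0.03 within the shallow libraries, sets formed from excitatory neurons. The oligodendrocyte and precursor calls were lost without CTRL replicate 1 (0.11 and 0.52) or DTA replicate 3 (0.09 and -0.14). The microglial call was lost without CTRL replicate 1 (0.44), CTRL replicate 2 (0.43), DTA replicate 2 (0.33) or DTA replicate 3 (0.22). The endothelial call was lost without CTRL replicate 1 (-0.08), CTRL replicate 2 (-0.19), DTA replicate 1 (-0.12) or DTA replicate 2 (-0.23). In newly formed oligodendrocytes the list had a median of 0.25 (adjusted p 0.461).

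The GABA and glutamate receptor lists were lower in inhibitory neurons and the neuropeptide list in excitatory neurons. GABA receptor genes fell in inhibitory neurons by a median of -0.23 with 12 of 15 lower (0.00685; 0.702 with an estimated correlation), led by Gabrb1 at -0.53 (SE 0.205), with 0 past the threshold adjusted over the list alone. Without CTRL replicate 2 the median was -0.15 and the call was lost, and without DTA replicate 3 it was -0.08. Genes of glutamate receptors and the postsynaptic density fell there by a median of -0.09 (0.0242; 0.80 with an estimated correlation), with 0 members past the threshold adjusted over the list alone, a call lost without CTRL replicate 2 (-0.02), DTA replicate 1 (-0.05) or DTA replicate 3 (-0.01). They were higher by 0.24 within the deep and lower by 0.40 within the shallow libraries. In excitatory neurons the GABA receptor median was 0.01 (mean -0.01, direction lower, adjusted p 0.896) and that of the glutamate receptor list -0.01 (mean 0.05, direction higher, 0.896). Neuropeptide genes fell in excitatory neurons by a median of -0.55 with 9 of 14 lower (0.00373; 0.702 with an estimated correlation). Cort alone passed adjusted over the list, and the call was lost without CTRL replicate 2 (median 0.25) or DTA replicate 2 (-0.38); without DTA replicate 1 the median was -0.36. Cort is also among the 10 leading genes of the inhibitory clusters 13 and 17, and inhibitory neurons held a lower share of neurons in the same libraries. In inhibitory neurons the neuropeptide list had a median of 0.10 (adjusted p 0.732).

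Lists of stress and lipid genes were also called in some classes, in both directions. Heat shock genes fell in endothelial cells by a median of -0.45 with 12 of 13 lower (camera adjusted p 1.23e-05; 0.702 with an estimated correlation), a call lost without CTRL replicate 1 (-0.06). They rose in inhibitory and excitatory neurons by 0.41 and 0.22 (0.00473 and 0.00219; 0.750 and 0.702 with an estimated correlation), with Hspa8, a chaperone gene, at 0.78 (SE 0.262) and 0.54 (SE 0.210). These were lost without CTRL replicate 2 (0.24 and 0.09) and, in inhibitory neurons, DTA replicate 3 (0.21). In inhibitory neurons the list was lower by 0.17 within the deep and higher by 0.74 within the shallow libraries. The excitatory median was 0.14 without DTA replicate 1 and 0.37 without CTRL replicate 1. In newly formed oligodendrocytes myelin genes fell by a median of -0.33 with 16 of 16 lower (6.08e-05; 0.750 with an estimated correlation), led by Ermn at -1.05 (SE 0.437), and cholesterol synthesis genes by -0.25 (0.00299; 0.80). Both were lower in the deep libraries (-1.46 and -1.50) and higher in the shallow ones (0.04 and 0.35), and both calls were lost without CTRL replicate 1 (-0.15 and 0.18) or DTA replicate 2 (-0.09 and 0.14). Cholesterol synthesis had -0.62 without CTRL replicate 2 and -0.78 without DTA replicate 3. In oligodendrocytes glucocorticoid response genes fell by -0.30 with 6 of 8 lower (0.00473; 0.702 with an estimated correlation). Sgk1, a kinase gene induced by glucocorticoids, stood at -1.03 (SE 0.267) and passed adjusted over the list alone. That call was lost without CTRL replicate 1 (0.05) or DTA replicate 1 (-0.15), and the median was -0.83 without CTRL replicate 2. 

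Lists of immune genes were called as higher in further classes at the preset correlation. Interferon response genes rose in astrocytes by a median of 0.85 with 4 of 5 higher (camera adjusted p 0.00471; 0.702 with an estimated correlation), led by Ifitm3, a gene of antiviral defence, at 0.90 (SE 0.323); the call was lost without CTRL replicate 2 (0.95). Class I genes rose in astrocytes by 0.42 and in excitatory neurons by 0.33, with 5 of 5 higher in both (0.00317 and 0.0168; 0.702 and 0.702). B2m, the shared light chain, stood at 0.42 (SE 0.216) and 0.56 (SE 0.229). The astrocyte call was lost without CTRL replicate 2 (0.55), and the neuronal call without CTRL replicate 1 (0.41), CTRL replicate 2 (0.18) or DTA replicate 3 (0.11). In microglia the class I list had a median of 0.20 (adjusted p 0.0561). Inflammatory cytokine genes rose in endothelial cells by 0.30 with 7 of 8 higher (0.0179; 0.702), with Cxcl2 at 1.73 (SE 0.631), a call lost without CTRL replicate 1 (0.26), DTA replicate 2 (0.21) or DTA replicate 3 (-0.13), while the median was 1.82 without CTRL replicate 2. In astrocytes the cytokine list had a median of 0.64 (adjusted p 0.252). Adjusted over the list alone, 0 members passed in each of these.

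Lists of metabolic stress were called in neurons. Hypoxia and glycolysis genes rose by a median of 0.12 in inhibitory and 0.11 in excitatory neurons (camera adjusted p 0.0202 and 0.0228; 0.730 and 0.702 with an estimated correlation), with Eno1 at 0.92 (SE 0.208) and 0.77 (SE 0.330). Adjusted over the list alone, 1 and 0 members passed. The inhibitory call was lost without CTRL replicate 2 (0.14), DTA replicate 1 (0.12) or DTA replicate 3 (0.17), and the excitatory call without CTRL replicate 1 (0.16), CTRL replicate 2 (0.05) or DTA replicate 3 (0.09), with 0.06 without DTA replicate 1. In inhibitory neurons the list was lower by 0.06 within the deep and higher by 0.26 within the shallow libraries. Endoplasmic reticulum stress genes rose in inhibitory neurons by 0.18 (0.0204; 0.80), led by Pdia4, a folding enzyme gene, at 0.94 (SE 0.279), which passed adjusted over the list alone. That call was lost without CTRL replicate 1 (0.13) or DTA replicate 3 (-0.04). In excitatory neurons this list was not called (median 0.07, adjusted p 0.0722; lower by 0.10 within the deep and higher by 0.24 within the shallow libraries).

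The circadian clock list and further lists of synapses and glia showed no call. Circadian clock genes had medians from -0.19 in astrocytes (camera adjusted p 0.180) to 0.11 in microglia (0.766). In newly formed oligodendrocytes the median was 0.11, while the mean was -0.16 and the test gave lower. In endothelial cells, excitatory neurons and oligodendrocytes the medians were -0.01 each, with means of 0.09, 0.05 and 0.06 and a direction of higher. Synaptic vesicle genes had medians of 0.00 in excitatory and -0.08 in inhibitory neurons (adjusted p 0.672 and 0.416), dendritic spine genes 0.01 and 0.07 (0.690 and 0.534), and monoamine and acetylcholine receptor genes -0.01 and -0.02 (0.0952 and 0.896). Homeostatic microglia genes had a median of 0.12 (0.621), astrocyte transport genes 0.14 (0.0560), and oligodendrocyte precursor and division genes 0.00 (0.896). In mature oligodendrocytes the myelin median was 0.00 (0.801).

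The third comparison describes the same genotypes in the MC, with 1 library each, so no test was run and no difference has a replicate check. It compares those libraries, not the conditions, and its Poisson intervals cover counting error only. MC CTRL belongs to the shallow set and MC DTA to the deep set, so genotype and depth cannot be separated here. Cells of 1 class also came from different clusters: cluster 16 held 2.47% of the microglia of MC CTRL and 84.2% of those of MC DTA, and cluster 3 held 84.0% and 7.43% of their astrocytes. Of the 46 lists called in the PFC that had a value in the MC, 32 had the same sign there: 26 of 38 higher and 6 of 8 lower. The same lists recur over classes of the same libraries, so these are not separate results. The share of all lists that were higher in MC DTA was not set beside them, so the count does not show agreement between areas. In MC endothelial cells the class I genes had a median log2 ratio of 0.93 with 10 of 10 higher, at percentile 100 of 10000 random lists of like expression. H2-K1 stood at 1.11 (95% interval 0.79 to 1.45). In microglia the interferon response genes, which mark antiviral signalling, had a median of 1.75 with 12 of 12 higher (0.09 in the PFC, camera adjusted p 0.101), class I genes 0.87 and homeostatic genes 0.59 with 15 of 15 higher. Inflammatory cytokine genes had a median of 0.45 with 15 of 16 higher, with Cxcl2 at 0.55 (0.24 to 0.87) and Tnf at 0.44 (0.20 to 0.68). Reactive astrocyte genes had a median of 0.61 with 4 of 6 higher, and ribosomal protein genes in astrocytes -0.08, opposite to the PFC. Cort in excitatory neurons stood at -1.43 (-2.23 to -0.70; 67 and 20 counts).

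Single genes of the MC libraries with the largest ratios included some known from other cell types, and RNA carried over between cells was not measured. In excitatory neurons Bc1, a dendritic RNA, stood at 2.16 (95% interval 1.98 to 2.34), Xlr3b at 2.12 (1.67 to 2.59) and the neuropeptide gene Cartpt at 1.69 (1.45 to 1.93). The B cell gene Ighm stood at -2.76 (-3.11 to -2.42), Ptgds, an oligodendrocyte gene, at -2.25 (-2.56 to -1.95) and Sst, an interneuron gene, at -2.14 (-2.47 to -1.82). In inhibitory neurons the activity gene Fos stood at 1.64 (1.32 to 1.96), the opioid gene Penk at 1.60 (1.29 to 1.91) and AC160336.1 at 1.39 (1.06 to 1.74). Rpl29 stood at -1.72 (-1.93 to -1.52) and Nos1, a nitric oxide synthase gene, at -1.72 (-2.17 to -1.29). In astrocytes the Notch target Hes1 stood at 1.30 (1.09 to 1.52), Ntm at 1.23 (1.10 to 1.36) and Igfbp5 at 1.10 (0.62 to 1.60). The neuronal genes Pcp4, Mllt11 and Tmsb10 stood at -2.36 (-2.64 to -2.09), -2.04 (-2.48 to -1.62) and -2.03 (-2.50 to -1.59).

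The last comparison asks how the cells of the 2 cortical areas differ, with genotype as a covariate and 2 MC against 5 PFC libraries. In excitatory neurons Frzb, an inhibitor of Wnt signalling, was higher in the MC by a log2 fold change of 2.37 (SE 0.196; 60.6 ± 2.82 against 11.2 ± 3.13 CPM, SD; edgeR adjusted p 0.000167). Cux1, a transcription factor gene of upper cortical layers, was higher by 1.67 (SE 0.124; adjusted p 7e-05). Lower in the MC were Nnat, the gene of a neuronal membrane proteolipid, at -3.12 (SE 0.270; adjusted p 0.000259), Grp, which encodes a signalling peptide, at -2.71 (SE 0.165; 2.27e-05) and Efnb3, an axon guidance ligand gene, at -2.39 (SE 0.197; 0.000102). These 5 genes kept their calls without any 1 of the 7 libraries. Brinp3 was higher by 1.69 (SE 0.322; 0.0286) but was lost without PFC CTRL replicate 1 (1.58), PFC CTRL replicate 2 (1.66), PFC DTA replicate 2 (1.72), MC CTRL (1.27) or MC DTA (2.13). In all, 801 of 14147 genes were called, 443 higher and 358 lower in the MC, and the groups did not overlap for 785 of them. The count fell to 94 without MC CTRL and 97 without MC DTA. The areas also differed in their mix of cells: at a resolution of 2.0, clusters 4 and 15, with Grp among their leading genes, held 27 and 10 cells of MC CTRL and 5 and 9 of MC DTA, against 37 to 1075 and 71 to 306 per PFC library. Such a mix was not separated from changes within cells.

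**Figure D4:**
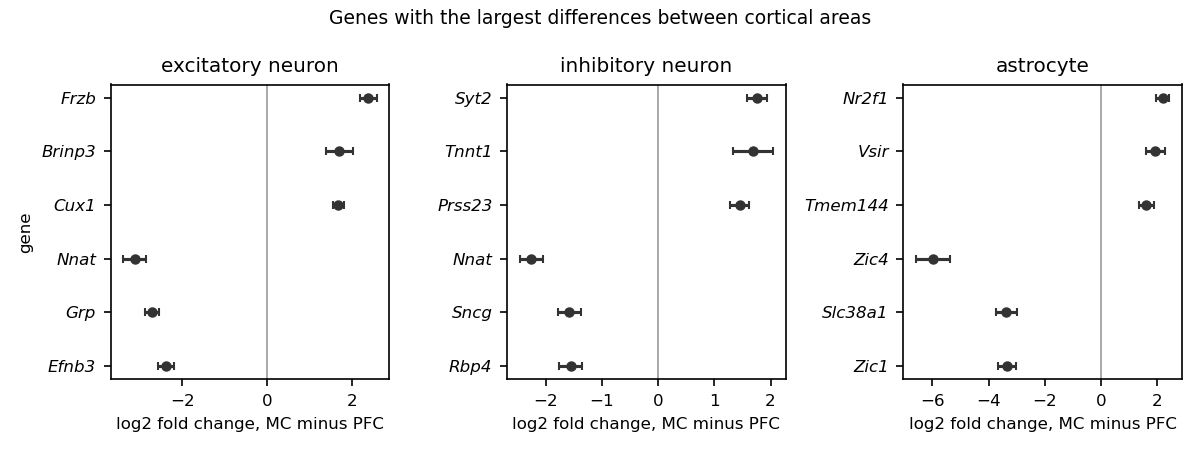
Log2 fold change (MC minus PFC) with its SE for the genes with the largest differences in excitatory neurons, inhibitory neurons and astrocytes. Nnat is lower in the MC in both excitatory (-3.12) and inhibitory neurons (-2.26), and Zic4 in astrocytes is the lowest (-5.98).

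Some receptor and synaptic genes were among those called between the areas in excitatory neurons. Among the lists, Htr2a, a serotonin receptor gene, was higher in the MC by 1.02 (SE 0.174; edgeR adjusted p 0.00609), and Cplx2, a gene of vesicle release, by 1.0 (SE 0.160; 0.00362). Drd1 and Htr2c, genes of a dopamine and a serotonin receptor, were lower by -1.21 (SE 0.241; 0.0130) and -1.54 (SE 0.329; 0.0271), and Cort by -1.52 (SE 0.234; 0.00314). Each lost its call without an MC library: Htr2a without MC DTA (0.54), Htr2c without MC CTRL (-1.03) or PFC DTA replicate 2 (-1.43). Cplx2 lost it without MC CTRL (0.94) or MC DTA (1.07), Drd1 likewise (-1.27 and -1.15) and Cort too (-1.70 and -1.40). Of 17 monoamine and acetylcholine receptor genes 5 were called, and 8 adjusted over the list alone. Of 24 glutamate receptor and postsynaptic genes 2 were called, and 7 adjusted over the list alone; for synaptic vesicle and GABA receptor genes the counts were 2 and 2, and 4 and 4 adjusted over the list alone. Immediate early genes had 1 called and 9 adjusted over the list alone. The subunit genes Grin1 and Grin2a of the NMDA receptor were higher by 0.52 and 0.51, Gabrd of the GABA receptor by 0.77, and Cplx1 by 0.75. Without MC CTRL these had 0.51, 0.55, 0.90 and 0.84, without MC DTA 0.53, 0.46, 0.62 and 0.63, and none stayed past the threshold in either case. Grin1 and Grin2a also lost their calls without PFC CTRL replicate 2 (0.51 and 0.47). Grin1 lost its call without PFC CTRL replicate 1 (0.54), and Grin2a without PFC DTA replicate 1 (0.52) or PFC DTA replicate 2 (0.49).

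In inhibitory neurons 246 of 11636 genes were called, 138 higher and 108 lower in the MC, and the groups did not overlap for 231. Syt2, a calcium sensor gene of fast-spiking interneurons, was higher by 1.77 (SE 0.179; 189 ± 26.0 against 53.0 ± 15.4 CPM, SD, n = 2 and 5; edgeR adjusted p 2.89e-05), and Prss23, a protease gene, by 1.45 (SE 0.170; 0.000116). Nnat, Sncg, a synuclein gene, and Rbp4, a retinol carrier gene, were lower at -2.26 (SE 0.205; 4.51e-06), -1.58 (SE 0.207; 0.000271) and -1.56 (SE 0.203; 0.000271). These 5 were called without any 1 of the libraries. Tnnt1 was higher by 1.69 (SE 0.358; 0.0408), a call lost without MC CTRL (1.32), MC DTA (2.02), PFC CTRL replicate 1 (1.77), PFC CTRL replicate 2 (1.42) or PFC DTA replicate 1 (1.73). Neuropeptide genes went both ways: Npy, of neuropeptide Y, was higher by 1.22 (SE 0.243; 0.0160) and Sst, of somatostatin, lower by -1.06 (SE 0.189; 0.00391). Without MC CTRL or MC DTA neither passed (1.23 and 1.22 for Npy, -0.94 and -1.19 for Sst), nor did Npy without PFC DTA replicate 1 (1.15). Cluster 20, led by Npy, held 6.03% and 4.81% of the neurons of MC CTRL and MC DTA and 2.13% to 3.46% of those of the PFC libraries, so the mix of subtypes differed too. Of 13 neuropeptide genes 5 were called, and 10 adjusted over the list alone. Of 19 circadian clock genes 2 were called, Hlf at 1.17 (SE 0.173; 0.000693) and Rora at 0.77 (SE 0.143; 0.00543), and 6 adjusted over the list alone. Without MC CTRL these had 0.83 and 0.87, Rora had 0.67 without MC DTA, and these calls were lost. GABA receptor genes had 2 called, and 9 of 15 adjusted over the list alone. The lower level of Nnat in the MC was not particular to neurons. In astrocytes it stood at -3.20 without MC CTRL and -3.03 without MC DTA, and in microglia at -3.47 with no filter on low counts. RNA carried over between cells was not measured. The count of genes was 28 without MC CTRL, 15 without MC DTA, 154 without PFC CTRL replicate 2 and 462 without PFC DTA replicate 2.

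In astrocytes 30 of 9943 genes were called, 13 higher and 17 lower in the MC. The transcription factor genes Zic4 and Zic1, which pattern the midline forebrain, were lower by -5.98 (SE 0.599; edgeR adjusted p 5.73e-05) and -3.35 (SE 0.320; 4.38e-05). The Zic4 fold rests on 1 count in the MC against 220 in the PFC, a ratio of 1.25% with an exact counting interval of 0.0315% to 7.04%. Slc38a1, a glutamine transporter gene, was lower by -3.37 (SE 0.370; 0.000932), and Nr2f1, a transcription factor gene of cortical area identity, was higher by 2.19 (SE 0.241; 0.000165). Slc38a1 lost its call without MC DTA (-2.86), and Nr2f1 without MC CTRL (2.09) or MC DTA (2.31). Vsir and Tmem144 were higher by 1.92 (SE 0.334; 0.0143) and 1.61 (SE 0.270; 0.0109), calls lost without MC CTRL (1.68 and 1.93) or MC DTA (2.31 and 1.27), and for Vsir without PFC DTA replicate 1 (1.98) or 2 (1.75). Of 8 reactive astrocyte genes, Vim and Fabp7 were called, lower by -1.72 (SE 0.249; 0.00375) and -1.36 (SE 0.213; 0.00792), and 4 adjusted over the list alone. Without MC CTRL (-1.71 and -1.30) or MC DTA (-1.72 and -1.42) neither passed. The count was 4 without MC CTRL, 3 without MC DTA, 16 without PFC DTA replicate 1 and 18 without PFC DTA replicate 2.

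Other glia and vessels gave few calls between the areas, and these counts do not show how far the areas differ there. In oligodendrocytes 1 of 9096 genes was called, Slco3a1, an organic anion transporter gene, higher in the MC by 1.24 (SE 0.165; 128 ± 3.93 against 56.5 ± 10.6 CPM, SD, n = 2 and 5; edgeR adjusted p 0.0133). It lost its call without MC CTRL (1.04), MC DTA (1.47), PFC DTA replicate 1 (1.26) or PFC DTA replicate 2 (1.23). The count there was 29 without PFC CTRL replicate 1, 2 without PFC CTRL replicate 2, 4 without PFC DTA replicate 3 and 3 without MC DTA. It was 0 without PFC DTA replicate 1, PFC DTA replicate 2 or MC CTRL. By edgeR 0 genes were called in newly formed oligodendrocytes, oligodendrocyte precursors, microglia and endothelial cells. At an unadjusted p under 0.05 these classes had 265, 247, 127 and 118 genes, and DESeq2 called 0. In oligodendrocytes DESeq2 called 3, Slco3a1, Hcn2 and Apoe, the latter pair singled out after their values were seen. In newly formed oligodendrocytes the edgeR count was 1, Mgp, without PFC CTRL replicate 1 (6.32) or PFC DTA replicate 2 (6.03), a gene singled out after its values were seen.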

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

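The tests weighed here were all chosen after seeing results except a pair written before, on short transcripts and on leukocyte genes. The share of neurons that were inhibitory was higher by 4.29 percentage points in the MC DTA library than in MC CTRL, while each PFC DTA library lay below each PFC CTRL library. Nuclear genes of oxidative phosphorylation in newly formed oligodendrocytes had an MC median log2 ratio of -0.0826, while each PFC DTA library lay above each CTRL library. These came up because the 2 areas moved in opposite directions, and the differences between areas were not tested. Unnamed clusters, outside the comparisons of classes, came up where their share in a DTA library had a 95% interval above those of the CTRL libraries of its area; smaller excesses are not listed. The cluster led by haemoglobin genes held 12.6% of PFC DTA replicate 1 and 33.0% of PFC DTA replicate 3, and the cluster led by neutrophil genes held 7.03% of PFC DTA replicate 3 and 0.469% of MC DTA. The cluster with astrocyte and excitatory neuron genes held 3.05% of PFC DTA replicate 2 and 4.22% of MC DTA, and a cluster with haemoglobin and endothelial genes held 0.895% of MC DTA.

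Ribosomal protein genes were higher in PFC DTA than in CTRL by their list median in all 8 classes tested, though single libraries of the genotypes overlapped in each class. For a bias towards short transcripts, the list median lay above the 95th percentile of sets matched on length and expression in 8 of 8 classes. Genes matched on length thus rose less than the list by their median. The sets were drawn gene by gene, so their percentile does not allow for genes that move together. A part played by length stays open, since the matched sets rose by 0.23 against 0.38 for the list in microglia and by 0.111 against 0.205 in inhibitory neurons. They fell by 0.025 in endothelial cells and rose by 0.023 to 0.065 in the other 5 classes, and their genes had a median length of 724 to 766 nt against 628.5 nt. Depth stays open. The list was higher within both the deep and the shallow libraries in 8 classes. These sets were formed from excitatory neurons, in which the DTA libraries were also the deeper ones within each set. Median UMI counts per excitatory neuron were 12508.5 in DTA against 11457 in CTRL, and 4104 and 5612 against 3565. Other classes did not all keep this order. In microglia PFC DTA replicate 1 had fewer counts per cell (151100 in 139 cells) than PFC CTRL replicate 2 (786689 in 585). The sets thus do not compare libraries of like depth in every class. A dependence on 1 library stays open. The median stayed above 0 without any 1 library in 6 classes, but fell to -0.063 in excitatory neurons and -0.054 in endothelial cells without PFC CTRL replicate 2. Reads of pseudogenes and an effect of the ablation were not tested and stay open.

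Class I genes were higher in PFC DTA endothelial cells. A single library is argued against, as the list median was at least 0.35 with any 1 left out. The smaller of the differences within a depth set was 0.53, but these sets were formed from excitatory neurons and endothelial cells did not follow them. PFC DTA replicate 1 had fewer counts per endothelial cell (279474 in 178 cells) than PFC CTRL replicate 2 (693952 in 401). PFC DTA replicate 3, of the shallow set, had more (514420 in 143) than PFC CTRL replicate 1 of the deep set (434519 in 161). Depth thus stays open, though PFC DTA replicate 1 had more class I CPM (3968) than PFC CTRL replicates 1 and 2 (2175 and 1968) at fewer counts per cell. For RNA of leukocytes, the test written before asked whether 7 leukocyte genes were higher by at least the list median; they were, by 0.68, as this explanation needs. By amount, at the ratio in the cluster led by MHC class II genes, their rise carries 0.959% of the rise in class I CPM. This test was added after that result, and the 7 genes include MHC class II genes themselves. It speaks only for cells like that cluster, so RNA of other leukocytes stays open. An effect of the ablation in both areas may be a candidate explanation, with an MC median of 0.93 from 1 library per genotype, the DTA one being deep and the CTRL one shallow, and it remains a hypothesis found and tested on the same data.

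The share of neurons that were inhibitory was lower in the PFC DTA libraries. Uneven depth could play a part: the smallest difference within a depth set was 1.5 percentage points, between libraries whose intervals overlapped. Survival of neuron types during dissociation was not tested, and loss of these cells to unnamed clusters is left open here.

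For the PFC genes, 10 splits of the 5 libraries into 2 and 3 are too few for a share under 0.05. The real split gave 0 genes over the 8 classes, so that all 10 splits had to give as many, and the highest other gave 332. That split set PFC CTRL replicate 2 and PFC DTA replicate 3 against the rest, with 214 of its genes in astrocytes and 104 in microglia, which points to a structure of the samples whose origin was not tested.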

How the results depend on the processing

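The term for the deep and shallow libraries and the shares of named cells or neurons were chosen after seeing the data. With no filter on low counts, 76 PFC genes were called where the main setting called 0: 16 in inhibitory neurons, 22 in astrocytes, 15 in oligodendrocytes, 4 in newly formed oligodendrocytes, 6 in precursors, 10 in microglia and 3 in endothelial cells. The endothelial genes were AC160336.1, Bach1 and Igfbp3. Thinning to equal numbers of cells called 1, Yjefn3 in inhibitory neurons, and the depth term called 2, Pdxp and Rps29 in precursors; these genes were singled out after their values were seen. DESeq2 called 1 gene in astrocytes and 1 over all cells. With an estimated correlation, 0 lists were called, against 47. The unnamed share, the 1 share called, gave 0 at resolutions of 0.5 and 2.0, with the replicate block, with the depth term and with named cells as the denominator. The cause was not tested.

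Replicate numbers were treated as not pairing these libraries, since only 2 numbers are shared and the labels do not state a link. Correlations of the deviations of same-numbered libraries were 0.111 and 0.111 in excitatory neurons, 0.091 and 0.076 in inhibitory neurons, 0.268 and 0.204 in newly formed oligodendrocytes and 0.101 and 0.153 in endothelial cells. They went both ways in astrocytes (0.208 and -0.05), oligodendrocytes (0.013 and -0.023), precursors (0.008 and -0.046) and microglia (0.152 and -0.207), so a link is not excluded. The replicate block called 27 PFC genes: 13 in inhibitory neurons, 6 in newly formed oligodendrocytes and 8 in microglia. With it the early genes in precursors had a median of -0.125.

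For the areas, no filter called 483 genes in inhibitory neurons, 148 in astrocytes, 25 in oligodendrocytes, 10 in newly formed oligodendrocytes, 4 in precursors, 1 in microglia and 6 in endothelial cells. Thinning called 151, 3 and 5 in inhibitory neurons, oligodendrocytes and newly formed oligodendrocytes. With doublets kept there were 19 in astrocytes and 1 in newly formed oligodendrocytes, and resolutions of 0.5 and 2.0 gave 16 and 8 in astrocytes. In oligodendrocytes the test that is not robust called 2 and DESeq2 3.

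Leaving out each library in turn gave 1 to 300 PFC genes: 0 to 8 in excitatory neurons, 1 to 14 in inhibitory neurons, 0 to 7 in astrocytes, 0 to 189 in oligodendrocytes, 0 to 3 in newly formed oligodendrocytes, 0 to 71 in precursors and 0 to 22 in endothelial cells. Lists called ranged from 27 to 51, shares called from 0 to 1, and the difference in inhibitory neurons as a share of kept cells from -6.64 to -2.35 points. For the areas the ranges were 118 to 1265 in all, 94 to 932 in excitatory neurons, 15 to 462 in inhibitory neurons, 3 to 44 in astrocytes, 0 to 29 in oligodendrocytes and 0 to 1 in newly formed oligodendrocytes. Where PFC CTRL replicate 1 or 2 or an MC library was left out, the lone library was assumed to vary like the other groups. The cause was not tested.

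List medians changed sign or direction when a library was left out. Without PFC CTRL replicate 2, oxidative phosphorylation had -0.079 in inhibitory and -0.052 in excitatory neurons, with highest values of 0.484 and 0.414 over the libraries left out. Ribosomal proteins had -0.054 in endothelial cells and -0.063 in excitatory neurons (highest 0.491 and 0.228). The glutamate receptor list in inhibitory neurons had -0.022 there, with the opposite direction by camera, and ranged from -0.267 to -0.013. Without PFC CTRL replicate 1, cholesterol synthesis in newly formed oligodendrocytes had 0.182 (lowest -0.782) and glucocorticoid response in oligodendrocytes 0.053 (lowest -0.826). Without PFC DTA replicate 2, cholesterol synthesis had 0.144 and ribosomal proteins in excitatory neurons -0.021. Without PFC DTA replicate 3, the early genes in precursors had -0.139 (highest 1.013). The cause was not tested.

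Over all settings, the genes named for the PFC stayed on their side of the threshold in 162 recomputed values and passed it in 6, of which 4 were with no filter, 1 with the replicate block and 1 without PFC CTRL replicate 1. Called lists kept their call in 416, lost it in 134 and changed direction in 11, besides 40 of 41 and 41 of 42 kept at resolutions of 0.5 and 2.0 and 47 of 47 with the test that is not robust. Genes named for the areas kept their call in 588 and lost it in 125, all in the same direction. Keeping every deposited cell moves nothing, as the filter removed 0 cells. Endothelial cells had no value at a resolution of 0.5, nor newly formed oligodendrocytes at 2.0, nor for the areas at either. For microglia 31.8% of genes had an interval within 2-fold, the lowest percentage of the 8 classes.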
